A study of Mus musculus with 6 samples.

How the data were processed

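Chromatin accessibility was measured in single cells of the mouse mammary gland by ATAC-seq, in which the Tn5 transposase inserts adapters into open chromatin so that counts mark accessible sites. Per the labels' protocols, the inguinal glands (number 4) of 4 female FVB/NJ mice aged 10 weeks were pooled, digested with collagenase at 2 mg/ml and trypsin, and stained for CD49f and EpCAM, which part basal from luminal epithelium, and for the endothelial, leukocyte and erythroid markers CD31, CD45 and Ter119. Basal and luminal cells were sorted separately and taken through the Chromium droplet protocol to 3 libraries each, with about 50000 reads aimed at per cell. The gates themselves are not given in the sources used here. Nothing in the labels says that the 3 libraries of a sort came from separate animals. The p-values therefore measure the spread between libraries, which may be technical.

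The deposited values are whole counts per peak and cell barcode, not normalized. Cell Ranger ATAC 1.1.0 and the mouse build mm10 are named in the submitters' processing notes. The cell filter, the peak calling, any equalisation of depth between libraries and any shift of the cut sites for the transposase are not given in the sources used here. All 6 files share 1 list of 127752 peaks, with a median length of 701 bp and a range of 2 to 60468 bp. Of the values above 0, between 91.1% and 93.9% were even numbers, so most fragments appear to be counted by both ends, and a count is not an independent molecule. Every barcode had at least 2501 counts, which leaves the low-count barcodes outside what was analysed here. The files held 21260 barcodes, taken as cells, and total counts ran from 19933799 to 128833670 per library. These totals limit counting error only.

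Peaks were compared with the mouse gene table of assembly GRCm38.p6, which is the same build as mm10. Of its 49997 rows, 34614 protein-coding and long non-coding genes with a unique symbol on chromosomes 1 to 19, X and Y were used. The table gives a start and an end for each gene, but no strand, transcription start or exons were used here. The design asked for counts over the gene body and 2 kb upstream of it, and without strand the window was the gene body and 2 kb at both ends. A gene's count was the sum over the peaks that overlap its window, and 25719 genes had at least 1 peak. A peak in the windows of several genes was counted in each of them, which held for 11% of the peaks. The share of a gene's counts that lies in such peaks is given in the results for genes named there with a value over their window where it was above 50%, and for some others. Of genes named only after the results, Itgb4, Slc2a1, Actg2, Notch4, Ndufa4l2, Cfd and Mcam had shares from 52.9% to 100%. In place of promoter, exon and intron classes, peaks were sorted into those within 1 kb of either end of a protein-coding gene, those inside a protein-coding gene only and those outside protein-coding genes. As a check of the build, 13.9% of the peaks lay within 1 kb of a gene end, against 7.6% after a shift of 100 kb.

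Counts were summed over the cells of each library, since cells are not replicates. Sums were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, after filterByExpr and TMM normalization, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. Levels are CPM after TMM, as mean ± SD over libraries, and fold changes are log2 values with the standard error from the F statistic. Relative to scaling by library size alone, TMM moved the median log2 fold change of peaks by 0.21, that of genes by 0.08 and that of genes between the luminal classes by 0.02, so all changes are relative to the TMM centre. Gene lists, 19 in number, were tested with camera of limma 3.58.1 on log2 CPM (prior count 3), with a preset inter-gene correlation of 0.01 and, as an alternative, an estimated one.

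Cells were clustered on binary peak values with TF-IDF weights and a truncated singular value decomposition (30 components, the first left out because its correlation with log depth was 0.99), 15 nearest neighbours and the Leiden method (leidenalg 0.10.2, resolution 0.2). The fourth component still had a correlation of 0.54 with log depth. Every cell passed the minimum of 500 counts. A marker counted as raised in a cluster at 1.5-fold over the mean of the other clusters, with 3 CPM added to both and at least 2 CPM in the cluster. A cluster took the name of the class with the most raised markers, if that class was basal, secretory, hormone responsive or immune. The markers were fixed before the data were examined, but the resolution and this way of naming were set afterwards. Cluster 4 carried markers of several types and kept its number. Its most raised markers by count were endothelial (9), ahead of basal (8) and pericyte (7) ones. Shares of cells were compared by exact two-sided permutation tests, for which 0.1 is the smallest p that 3 against 3 libraries allow, and shares of single libraries have exact (Clopper-Pearson) 95% intervals. Doublets were scored by simulated pairs of cells of the same library. All cells were kept in the comparisons, and an alternative left out the highest scores at 0.8% per 1000 barcodes, which was 0.88% to 5.62% of a library.

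For the comparison within the luminal libraries, cells were clustered anew on peaks of the odd-numbered chromosomes and X, or of the even-numbered ones. Each of these clusters took the name of the marker list with the highest mean log2 ratio to the other clusters, over all chromosomes. Genes were tested on the chromosomes not used for the clustering, with the library as a block because both classes of a library are cells of the same pool. The 2 sets of classes placed 99.52% of 7041 cells in the same class.

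Named genes follow a rule fixed before the data were examined. It takes, in each direction, the 12 protein-coding genes of largest absolute log2 fold change among those past the threshold, with average log2 CPM at or above the median and no overlap between the groups (or every library pair in the same direction). It also takes 2 to 4 members per list, of which the 3 with the largest change among those past the threshold and the 1 of highest level among the others were used here, a number settled after the data were examined. Peaks are the 3 of largest change in each direction at or above the 75th percentile of level and without overlap, plus the peak of smallest p for 11 marker genes.

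The libraries were compared before they were averaged. Over peaks open in at least 50 cells, the numbers of cells with a count differed between libraries of a sort with a mean chi-square per degree of freedom of 0.9 to 1.01, so on average over peaks every pair agreed within sampling noise. This mean does not cover the shares of cell classes, which differed between luminal replicates 2 and 3 beyond their exact intervals. The libraries shared few barcodes, at most 44 for a pair of the same sort and 24 for a pair of different sorts, so they hold different cells. They were kept as 3 libraries per sort.

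On simulated counts with 200 changed features among 122940 peaks, the test recovered 24% of peaks changed 1.25-fold, 60% of those changed 1.5-fold and 94% of those changed 2-fold, and called 7 unchanged peaks. Among 25568 genes it recovered 86% of those changed 1.25-fold and 90% of those changed 1.5-fold and called 9 unchanged genes, and among 25088 genes of the luminal classes 60%, 92% and 8. Simulated counts with no list changed gave 0 called lists, and 1 lowered list was called. Simulated genes were drawn independently of each other, so this cannot test the preset correlation between genes. Nor do the rates above carry over directly, since 200 features were changed while 82% of the peaks in the data differed. Alternatives were DESeq2 1.42.0, no TMM, no count filter, a replicate block, cells with a count in place of counts, cells matching their sort, thinning to the smallest library and leaving out each library. Added after seeing the data were a test against a 1.5-fold change (glmTreat), gene bodies without flanks, leaving out each library for the shares and for the lists of the luminal classes, and others named with their results. Motifs and GC content were not analysed here.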

Results

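The mammary epithelium is a bilayer in which contractile basal cells surround luminal cells that line the ducts, and the luminal layer holds a hormone responsive and a secretory cell type. The series profiled chromatin accessibility in both layers, as 3 single-cell libraries of sorted basal cells and 3 of sorted luminal cells. Glands of 4 mice were pooled, and the sources used here do not say whether 1 pool gave all the libraries. The files held 4017, 3002 and 7030 cells of basal replicates 1 to 3 and 1131, 3810 and 2270 cells of luminal replicates 1 to 3. Total counts in peaks were 73994821, 57564834 and 128833670 in the basal libraries and 19933799, 57495596 and 37439391 in the luminal ones. The median count per cell ran from 15280.5 to 16609 in basal and from 12403 to 14914 in luminal libraries. Over peaks, libraries of 1 sort differed on average by no more than sampling noise, and the labels do not tie them to separate animals. The adjusted p-values of the tests on summed counts can therefore be small for small differences too, and fold changes carry more of the information. All coordinates are in the mouse build mm10.

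The first question was which cell types the 2 sorts held. Nearly all cells of the basal sort fell into 1 basal-like cluster, and the cells of the luminal sort fell into a secretory-like and a hormone responsive-like cluster. Basal-like cells, in which 22 of 28 basal markers were raised, made up 94.5% ± 0.42 (SD, n = 3) of the basal libraries and 0.54% ± 0.23 of the luminal ones. Secretory-like cells, with 13 of 18 secretory markers raised, made up 60.1% ± 2.5 of the luminal and 0.414% ± 0.17 of the basal libraries. Hormone responsive-like cells, with 13 of 14 markers raised, made up 37.6% ± 2.3 of the luminal and 0.304% ± 0.093 of the basal libraries. The sorts themselves set these shares. Each of the 3 differences had an exact permutation p of 0.1, the smallest that 3 against 3 libraries allow. Within the luminal sort, shares differed beyond counting error, with 58.5% (exact 95% interval 56.9 to 60) secretory-like cells in luminal replicate 2 and 63% (61 to 65) in luminal replicate 3. In the luminal libraries there were 1.56, 1.47 and 1.79 secretory-like cells per hormone responsive-like cell.

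The remaining cells carried markers of other cell types. Immune-like cells, with 7 of 12 immune markers raised and the leukocyte gene Ptprc first among the leading genes, made up 1.68% ± 0.073 of the basal and 1.21% ± 0.49 of the luminal libraries (exact permutation p = 0.4, n = 3 each). The stain for CD45, which Ptprc encodes, bears on this share, and luminal replicate 1 with 1.77% lay apart from luminal replicates 2 and 3 with 0.892% and 0.969%. The difference of 0.473 percentage points was 0.752 without luminal replicate 1 and 0.315 without luminal replicate 2. Cluster 4, with 489 cells, carried 9 of 12 endothelial, 7 of 10 pericyte and 8 of 28 basal markers and was left without a name. It made up 3.15% ± 0.37 of the basal and 0.576% ± 0.29 of the luminal libraries (exact permutation p = 0.1, n = 3 each), although CD31, an endothelial surface protein, was among the stains. Median counts per cell were 7010 in immune-like cells and 17642 in cluster 4, against 15755 in basal-like cells.

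**Figure D1:**
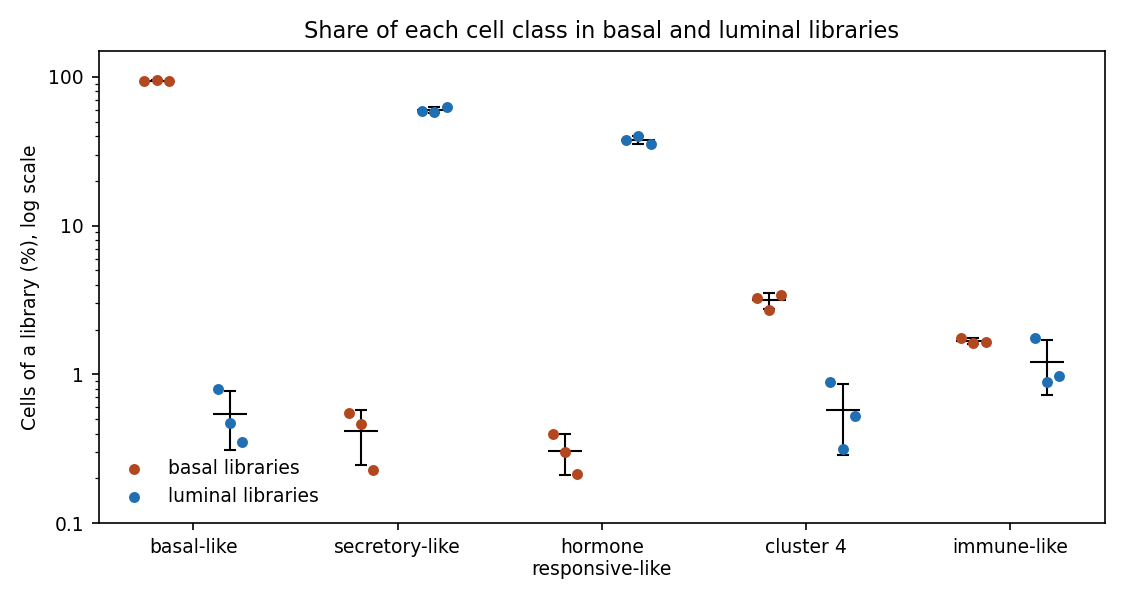
Share of the cells of each library (percent, log scale) in the 5 cell classes, with 1 point per library, the mean as a horizontal line and bars of 1 SD. Basal-like cells made up 94.5% of basal libraries, and secretory-like and hormone responsive-like cells made up 60.1% and 37.6% of luminal ones.

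The main contrast of the series was accessibility in sorted basal against sorted luminal cells, first peak by peak. Of 122940 peaks tested, 100867 differed (edgeR, adjusted p under 0.05), with 50206 higher in luminal and 50661 higher in basal libraries. Without TMM 58523 were higher in luminal and 41849 in basal libraries. By the test against a 1.5-fold change, chosen after seeing the data, 37487 were higher in luminal and 33599 in basal libraries. The libraries of the 2 sorts did not overlap at 82.4% of the peaks, where chance gives 10%. Peaks within 1 kb of an end of a protein-coding gene differed less in size than the others. Their median absolute log2 fold change was 0.38, and 22.9% differed over 2-fold, against medians of 1.21 inside protein-coding genes and 1.22 outside them with 56.4% and 56.5% over 2-fold. They were also the more open peaks, with a median of 21 CPM against 2 and 2.01 CPM. Among them 9758 were higher in basal and 4335 in luminal libraries, but this division rests on the scaling, since without TMM 6074 were higher in basal and 6934 in luminal libraries.

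At 11 marker genes of the 2 layers, the single peak of smallest p was several-fold more open in the layer that the marker belongs to. The peak over the basal keratin gene Krt5 (chromosome 15, 101703906 to 101719121, spanning the whole gene) had 157.9 ± 2.83 CPM in basal and 9.21 ± 0.457 CPM in luminal libraries (SD, n = 3 each). The corresponding peak at Krt14 (chromosome 11, 100198427 to 100210710) was 5.71-fold higher in basal libraries. A peak inside Trp63, which encodes the basal transcription factor p63 (chromosome 16, 25834411 to 25836125), was 17.3-fold higher, and one inside the smooth muscle actin gene Acta2 (chromosome 19, 34245646 to 34249776) was 8.97-fold higher. In luminal libraries, the peak at the keratin gene Krt18 (chromosome 15, 102030276 to 102035301) was 13.2-fold higher, and the peak at Krt8 (chromosome 15, 101990502 to 101999534), which also overlaps Krt78, was 6.36-fold higher. A peak inside the prolactin receptor gene Prlr (chromosome 15, 10191832 to 10192863) had 22.6 ± 0.881 CPM in luminal and 0.785 ± 0.227 CPM in basal libraries. Peaks inside Elf5, a transcription factor gene of secretory cells (chromosome 2, 103435885 to 103436955), and inside the oestrogen receptor gene Esr1 (chromosome 10, 4624690 to 4625826) were 24.1-fold and 14.3-fold higher in luminal libraries. A peak within 2 kb of the progesterone receptor gene Pgr (chromosome 9, 8970126 to 8970789) was 16.6-fold higher, and one at the receptor gene Kit (chromosome 5, 75574306 to 75577498) was 4.14-fold higher. These are single peaks, chosen by their p where a window held several. The whole gene windows differed less than these peaks for all 11 but Kit, whose window was 6.13-fold higher in luminal libraries. The windows of Krt5 and Krt14 hold only that 1 peak, so no peak was chosen there. Their slightly lower window folds, 15.3 and 5.16, come from the separate scaling of peaks and genes. Over the window, Trp63 (33 peaks) was 2.43-fold higher in basal libraries, and Elf5 (13 peaks) and Esr1 (14 peaks) were 2.76-fold and 1.3-fold higher in luminal libraries. The window of Pgr (4 peaks) did not pass, with 35 ± 1.41 CPM in basal and 36.4 ± 2.04 CPM in luminal libraries. The edgeR adjusted p-values of these 11 peaks ran from 6.9e-50 for Krt5 to 3.8e-28 for Pgr.

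Among the more open peaks, the 3 largest changes toward luminal were inside Ankrd27 (chromosome 7, 35596456 to 35597672; 51.5-fold), inside Galnt9 (chromosome 5, 110572443 to 110573443; 45.9-fold) and inside Ap3d1 (chromosome 10, 80727238 to 80728599; 43.8-fold). The 3 largest toward basal were inside the long non-coding gene Gm35940, outside protein-coding genes (chromosome 9, 41832102 to 41833428; 68.6-fold) and, as a pair, inside the sodium-calcium exchanger gene Slc8a1 (chromosome 17, 81579847 to 81581153, 61.3-fold, and 81541912 to 81543417, 61.2-fold). The peak in Ankrd27 varied most, at 16 ± 2.63 CPM in luminal and 0.287 ± 0.186 CPM in basal libraries (SD, n = 3 each).

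Summed over gene windows, 20426 of 25568 genes differed (edgeR, adjusted p under 0.05), with 10416 higher in luminal and 10010 in basal libraries, or 12430 and 8302 without TMM. Against a 1.5-fold change 7729 did, with 4127 higher in luminal and 3602 in basal libraries. Among the 12 named genes higher in luminal libraries, Arhgef38 (chromosome 3, 133112278 to 133234949) led with 94.4 ± 2.75 CPM against 4.05 ± 0.413 CPM, a 23.8-fold difference. Myo5c, an unconventional myosin gene, was 11.6-fold higher. The nucleoside transporter gene Slc28a3 and the sodium-glucose transporter gene Slc5a1 were 7.72-fold and 5.92-fold higher, and Prlr was 6.06-fold higher. The others were Lcp1, Galnt9, Rhov, Mboat1, the desmosome gene Pkp2, Cytip and Pik3ap1, from 7.26-fold for Lcp1 to 5.02-fold for Pik3ap1. Of the counts of Lcp1 and Myo5c, 55.4% and 47.4% lay in peaks shared with a neighbouring gene.

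Among the 12 named genes higher in basal libraries, the keratin genes Krt17, Krt5 and Krt42 led together with Cpxm2. Krt5 (chromosome 15, 101707069 to 101712905) had 127.1 ± 2.2 CPM in basal and 8.22 ± 0.433 CPM in luminal libraries, a 15.3-fold difference. Krt17 was 15.9-fold higher, but its only peak is shared with a neighbour, as are 81.6% of the counts of Krt42, so these keratin genes cannot be told apart here. Tenm3, Oca2, Tmem45a, the chemokine gene Cxcl14, the homeobox gene Irx4, Vgll3, the calponin gene Cnn1 and Igfbp3 followed, with log2 fold changes from -3.41 for Tenm3 to -2.80 for Igfbp3 (luminal minus basal). Of the counts of Igfbp3, 90.2% lay in shared peaks. The edgeR adjusted p-values of the 24 named genes ran from 1.3e-54 for Arhgef38, Krt5 and Krt42 to 1e-42 for Oca2.

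The fixed lists of basal genes moved together. All 12 genes of basal keratins and identity were higher in basal libraries, with a median log2 fold change of -1.42 (camera, adjusted p = 8e-06; adjusted p = 0.13 with an estimated correlation). Krt14 was at -2.37 ± 0.04 (SE). All 16 contractile genes were higher in basal libraries, with a median of -1.36 (camera, adjusted p = 8.3e-07; adjusted p = 0.13 with an estimated correlation), led by Cnn1 at -2.81, Acta2 at -2.24 and the smooth muscle myosin gene Myh11 at -1.91. Of the 18 genes of basement membrane and hemidesmosome, 15 were higher in basal and 2 in luminal libraries (camera, adjusted p = 8.5e-05; adjusted p = 0.16 with an estimated correlation). Sparc, Col7a1 and the collagen IV gene Col4a2 were at -2.22, -1.94 and -1.86, and 89.6% of the counts of Col7a1 lay in shared peaks, while Nid1 was at -0.02 ± 0.07 and turned to 0.06 without TMM. Fibroblast markers, of which the list named Col1a2, Fbln1 and Dcn at -2.68, -2.19 and -2.10, stood beside these groups with 7 of 11 genes higher in basal and 4 in luminal libraries (camera, adjusted p = 0.23).

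Wnt and mesenchymal genes were also mostly higher in basal libraries. Of 22 Wnt receptors, ligands and targets, 18 were higher in basal and 2 in luminal libraries, with a median log2 fold change of -0.65 (camera, adjusted p = 5.7e-05; adjusted p = 0.17 with an estimated correlation). The R-spondin receptor gene Lgr5 had 88.1 ± 1.22 CPM in basal and 21.5 ± 1.28 CPM in luminal libraries (SD, n = 3 each), and Wnt10a and the Wnt target Nkd1 were at -1.79 and -1.43. The Wnt effector gene Tcf7l2 was at -0.04 ± 0.02 and turned to 0.04 without TMM. Of 12 mesenchymal genes, 10 were higher in basal libraries and 1, Zeb1 at 1.83, in luminal libraries (camera, adjusted p = 0.014; adjusted p = 0.16 with an estimated correlation). Cdh2 and Vim were at -1.69 and -1.01, and 99.6% of the counts of Vim lay in shared peaks. This list fell short of the threshold when gene bodies were taken without flanks (adjusted p = 0.068).

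The lists of luminal genes moved the other way. Of 18 pan-luminal genes, 16 were higher in luminal libraries and 2 did not pass, with a median log2 fold change of 0.87 (camera, adjusted p = 8.4e-06; adjusted p = 0.16 with an estimated correlation). The epithelial transcription factor gene Ehf was at 1.85, Krt18 at 1.68 and the claudin gene Cldn3 at 1.63, the last from shared peaks alone. Gata3, a luminal transcription factor gene with 99.1% of its counts in shared peaks, was at -0.04 ± 0.02, with 223.8 ± 4.55 CPM in basal and 218.2 ± 3.7 CPM in luminal libraries, and turned to 0.04 without TMM. Of 17 secretory genes tested, 13 were higher in luminal and 2 in basal libraries, with a median of 1.34 (camera, adjusted p = 0.002; adjusted p = 0.22 with an estimated correlation). The milk protein genes Csn1s1, Wap and Ltf had the largest folds but low levels, from 2.05 to 3.11 CPM in luminal libraries. Of 14 hormone responsive genes, 10 were higher in luminal and 2 in basal libraries, with a median of 0.34 (camera, adjusted p = 0.031; adjusted p = 0.41 with an estimated correlation). Prlr, the growth factor gene Areg and the forkhead factor gene Foxa1, with 78.2% of its counts in shared peaks, were at 2.60, 1.52 and 1.47, while the whole window of Pgr was at 0.06 ± 0.04 and at -0.20 with the gene body without flanks. The hormone responsive list did not pass without luminal replicate 2 (adjusted p = 0.071), with cells matching their sort (0.056) or with gene bodies without flanks (0.16).

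The other lists did not pass the test between basal and luminal libraries. Of 19 genes of milk lipid and lactose synthesis, 10 were higher in luminal and 5 in basal libraries (camera, adjusted p = 0.16), and 14 and 4 without TMM, with the fatty acid receptor gene Cd36 at 3.05, Lalba at 2.73 and Thrsp at 2.15, and with Acaca at -0.02, which turned to 0.06 without TMM. In the Notch pathway 8 genes were higher in luminal and 6 in basal libraries (adjusted p = 0.98), among them the ligand genes Jag2 and Dll1 at -2.34 and -1.38 and the receptor gene Notch3 at 0.78. Of 18 steroid and peptide hormone receptors, 7 were higher in luminal and 9 in basal libraries (adjusted p = 0.81), and 8 in each without TMM, with the oxytocin receptor gene Oxtr at -1.37. Proliferation genes divided 4 to 4 (adjusted p = 0.81), and without TMM 8 to 1 toward luminal libraries, with log2 fold changes of 0.52 for Aurka, which had 98% of its counts in shared peaks and was at -0.04 with gene bodies without flanks, and -0.40 for Top2a. Genes used in all cells divided 3 to 3 (adjusted p = 0.9), and without TMM 8 to 2 toward luminal libraries, with Gapdh at -0.41 and Ywhaz at 0.00. Counts adjusted over the list alone were the same as over all genes for every list but proliferation, where 2 in place of 4 genes were higher in basal libraries. For the Notch, hormone receptor, all-cell, pericyte and adipocyte lists, the median, the mean and the test did not all have the same sign.

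Marker lists of non-epithelial cells went both ways, and none passed the test (camera, adjusted p from 0.23 to 0.94). Among immune markers, 5 were higher in luminal and 4 in basal libraries, with Ikzf1 at 1.42 and Ptprc, at 0.551 ± 0.0935 CPM in basal and 0.845 ± 0.464 CPM in luminal libraries, not passing. Among endothelial markers 4 were higher in luminal and 5 in basal libraries, and 5 and 3 without TMM, with Erg at -1.99 and Cdh5 at 1.47. Pericyte markers divided 4 to 5, with Abcc9 at 3.38. Adipocyte markers divided 4 to 2, with Lep at -3.19 and Cidec at 2.47. Of 4 erythroid markers tested, 3 were higher in luminal libraries, with Slc4a1 at 1.94. Among the list genes named for this contrast, the counts of Gapdh lay in shared peaks alone, as did 96% of those of Thrsp, 68.9% of Ywhaz, 68.3% of Ikzf1, 65.8% of Jag2, 57.3% of Zeb1 and 55.2% of Acta2.

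**Figure D2:**
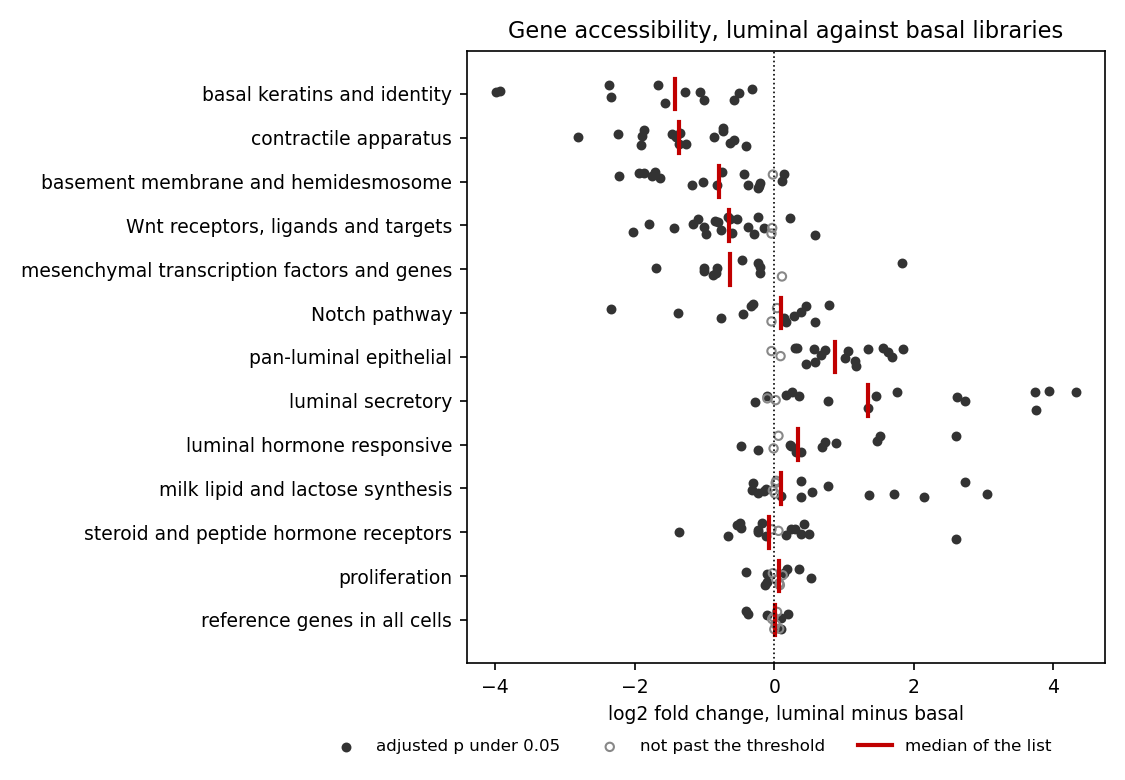
Log2 fold change of gene accessibility (luminal minus basal, horizontal axis) for each gene of 13 fixed lists, filled where the adjusted p was under 0.05, with the median of each list as a red bar. All 12 basal keratin and identity genes and all 16 contractile genes lie below 0, and 16 of 18 pan-luminal genes passed the threshold above 0.

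Within the luminal libraries, hormone responsive-like cells were compared with secretory-like cells of the same library. The cells were clustered on other chromosomes than those of the genes tested, while the clusters were named from markers on all chromosomes. Of 25088 genes, 15702 differed (edgeR with the library as a block, adjusted p under 0.05), with 7840 higher in hormone responsive-like and 7862 in secretory-like cells. Against a 1.5-fold change, 2030 were higher in hormone responsive-like and 3284 in secretory-like cells. In 75.5% of the genes all 3 libraries had the same direction, where chance gives 25%.

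The 12 named genes higher in hormone responsive-like cells were led by Ptpn5 and Sgsm1. Ptpn5, a tyrosine phosphatase gene, was 9.73-fold higher, with 82.9 ± 2.22 CPM against 8.48 ± 0.423 CPM (SD, n = 3 each), and Sgsm1 and Sec14l4 were 8.77-fold and 7.63-fold higher. The cadherin gene Cdh13, the sulfonylurea receptor gene Abcc8 and the neurexin gene Nrxn3 were 7.22-fold, 5.7-fold and 5.57-fold higher. Shisal1, the channel gene Asic2, Lrtm2, the tenascin gene Tnr, the neurotrophin gene Bdnf and the potassium channel gene Kcnh1 ran from 5.46-fold for Shisal1 to 4.13-fold for Kcnh1. All counts of Lrtm2, 63.6% of those of Ptpn5 and 50.7% of those of Cdh13 lay in peaks shared with a neighbouring gene.

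The 12 named genes higher in secretory-like cells were led by Mgam, a glucosidase gene, and Kit. Mgam had 53 ± 3.33 CPM in secretory-like and 5.9 ± 0.329 CPM in hormone responsive-like cells, an 8.75-fold difference, and Kit had 73.9 ± 1.85 and 8.8 ± 1.21 CPM, an 8.15-fold difference. Of the counts of Col9a3, 55.7% lay in shared peaks. Rftn1, the chemerin receptor gene Cmklr1, Sorcs3, Synpr, the collagen gene Col9a3, B3galt5 and the prostaglandin receptor gene Ptger2 ran from 7.56-fold for Rftn1 to 5.78-fold for Ptger2. The growth factor receptor gene Egfr (chromosome 11, 16752203 to 16913907) had 212.8 ± 3.74 CPM against 37 ± 5.38 CPM, a 5.63-fold difference with the smallest adjusted p of the comparison (edgeR, 1.3e-34). Ano3 and Sox10, the second from 1 shared peak, were 5.62-fold and 5.61-fold higher. Kit also belongs to the markers that named the secretory-like class.

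The lists that named the classes differed as their use for naming requires, so they are not findings. All 17 secretory genes tested were higher in secretory-like cells, with Csn1s1, Wap and Wfdc18 at log2 fold changes of -3.78, -3.70 and -3.46 (camera, adjusted p = 8.6e-07; adjusted p = 0.39 with an estimated correlation). Of 14 hormone responsive genes, 12 were higher in hormone responsive-like cells, with Pgr, Areg and Tbx3 (96.3% of its counts in shared peaks) at 1.72, 1.63 and 1.41 (camera, adjusted p = 6.8e-05; adjusted p = 0.39 with an estimated correlation). Prlr, at 91.7 ± 2.05 CPM in secretory-like and 94.3 ± 4.04 CPM in hormone responsive-like cells, was at 0.04 ± 0.05. No other list passed (camera), and 3 of them had an unadjusted p under 0.05, namely the contractile, milk synthesis and all-cell lists.

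Lists with members on both sides included genes with several-fold changes. Of 19 genes of milk lipid and lactose synthesis, 12 were higher in secretory-like and 5 in hormone responsive-like cells (camera, adjusted p = 0.13), with Lalba, Xdh and the lipoprotein lipase gene Lpl at -3.22, -2.08 and -1.90, and 3 of its genes, Lalba, Xdh and Btn1a1, are in the secretory list too. Contractile genes divided 12 to 3 toward secretory-like cells (adjusted p = 0.11), with Cald1 at -1.13, Oxtr at -1.02 and Myocd at 1.32. Of 12 basal keratin and identity genes, Egfr, Krt14 and Trp63 were higher in secretory-like cells, at -2.49, -1.25 and -1.07, and 4 were higher in hormone responsive-like cells (adjusted p = 0.79). Wnt genes divided 12 to 6 toward secretory-like cells (adjusted p = 0.33), with Lgr6 at -1.42, Tcf7l2 at -1.14 and Wnt5a at 1.09. Mesenchymal genes divided 6 to 3 (adjusted p = 0.4), with Zeb1, Vim and Zeb2 at -1.70, -1.36 and -1.27.

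Hormone receptor genes divided 9 to 5 toward secretory-like cells (adjusted p = 0.42), with the retinoic acid receptor gene Rarb at -1.72 and Pgr at 1.72. Pgr, Esr1 (at 0.67) and Prlr are also in the hormone responsive list that named the class. Notch genes divided 7 to 6 (adjusted p = 0.8), with Maml2 at -1.27, Dll1 at -1.19 and Mfng at 1.18. Basement membrane genes divided 7 to 9 (adjusted p = 0.65), with Nid1 at 1.60 and Col4a1 at -0.85. Of 18 pan-luminal genes, 6 were higher in secretory-like and 5 in hormone responsive-like cells, and 6 in each without TMM (adjusted p = 0.92; the median and the mean differ in sign), with Krt7 at 1.18 and Ehf at -1.09. Genes used in all cells were higher in hormone responsive-like cells for 6 of 12 (adjusted p = 0.19), with Ppia at 0.44, and 11 of 13 proliferation genes did not pass by edgeR (adjusted p = 0.81 for the list). The immune, endothelial, fibroblast, pericyte, adipocyte and erythroid lists had adjusted p-values from 0.27 to 0.89, with Ikzf1 at -1.69, Dcn at 1.66, Abcc9 at -2.64 and Cidec at 2.22 among their members. Over the list alone, counts changed in the mesenchymal list, where 7 in place of 6 genes were higher in secretory-like cells, and in the proliferation list, where Pcna no longer passed. The counts of Mfng and Pcna lay in shared peaks alone, as did 69.9% of those of Krt7, 68.9% of Col4a1, 68.3% of Ikzf1, 57.3% of Zeb1 and 55.6% of Zeb2.

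**Figure D3:**
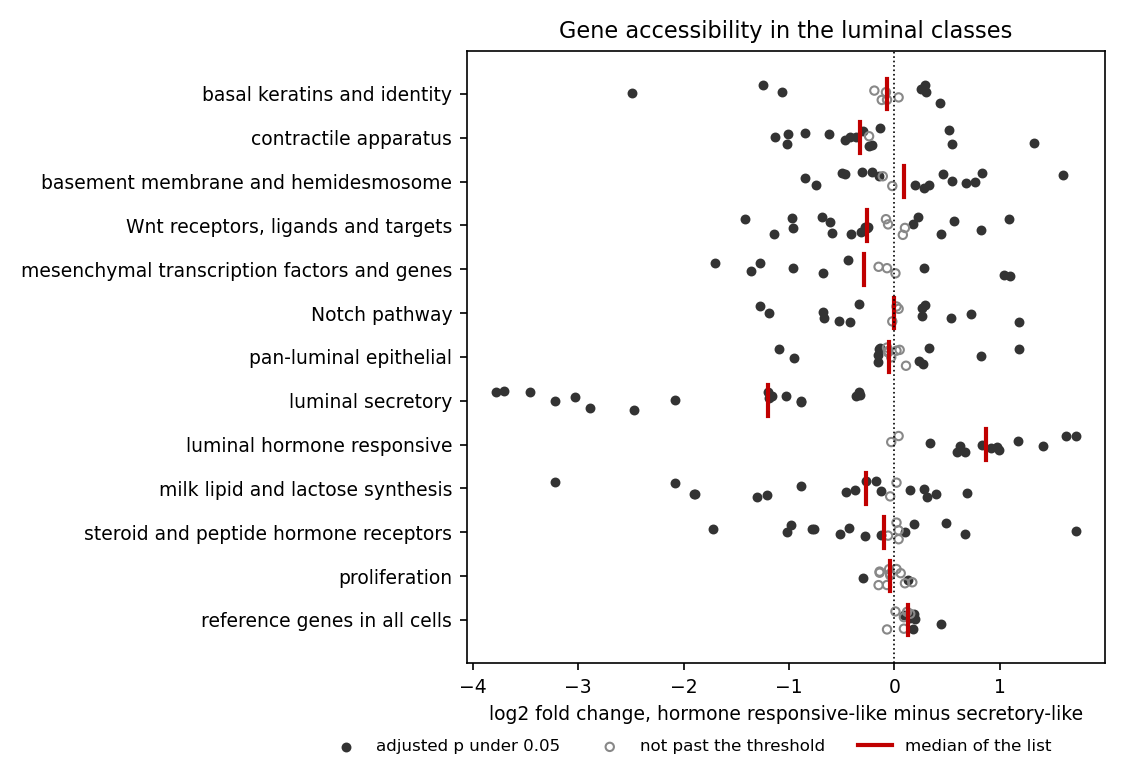
Log2 fold change of gene accessibility between the luminal classes (hormone responsive-like minus secretory-like, horizontal axis) for each gene of 13 fixed lists, filled where the adjusted p was under 0.05, with the median of each list as a red bar. All 17 secretory genes lie below 0, and each of the other lists has genes on both sides of 0.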

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

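The test against a 1.5-fold change, gene bodies without flanks, cells matching their sort for the lists, every alternative for the place of peaks, leaving out libraries for the shares and for the lists of the luminal classes, no TMM within the luminal classes and leaving out cells with marks of both classes were added after seeing the data. The counts of differing peaks (89943 to 102800, edgeR or DESeq2) and of genes (19047 to 20732) kept within 1.5 times their values of 100867 and 20426, as did those of genes between luminal classes (12634 to 15971 against 15702), apart from the test against a 1.5-fold change. By that test 71086 peaks, 7729 genes and, between the classes, 5314 genes passed, fewer because it asks for more. Of the 17 named peaks, all kept direction and side of the threshold in the 238 comparisons run. Of 1362 comparisons of 91 named genes between the sorts, 1304 did, 25 newly passed, 10 no longer passed and 23 reversed. Of 1034 comparisons of 94 genes between the luminal classes these numbers were 992, 7, 25 and 10. With an estimated correlation 0 of the lists passed in either comparison (camera; 5 and 2 of 19 at an unadjusted p under 0.05), against 8 and 2 with the preset value. Peaks within 1 kb of a gene end were 14% of differing peaks, 13% without TMM, 14.3% after thinning, 7.63% against a 1.5-fold change and 13.7% to 14.2% when leaving out a library. With the first component kept, the difference in shares (basal minus luminal) moved from -59.7 to -62.7 percentage points for secretory-like and from -37.3 to -34.2 for hormone responsive-like cells. Leiden clusters at resolution 0.1 or 0.4 took most of their cells' class at 0.2, so shares could hardly move. Where not stated otherwise, the cause was not tested.

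Reversals between basal and luminal libraries were in genes that had not passed, Aurka apart. Without TMM the log2 fold changes became 0.06 for Nid1 and Acaca, 0.04 for Gata3, Tcf7l2 and Rarb, 0.03 for Ndufa4l2 and 0.01 for Cfd. By cells with at least 1 count they became -0.02 for Xdh, 0.05 for Tcf7l2, -0.04 for Pcna and -0.00 for Ywhaz, and by DESeq2 -0.01 for Ywhaz. With gene bodies without flanks they became -0.17 for Xdh and -0.20 for Pgr, which then passed toward basal (edgeR), and -0.04 for Aurka, which no longer passed. Leaving out libraries gave -0.12 to 0.05 for Nid1 (above 0 without basal replicate 3 or luminal replicate 1), -0.01 to 0.05 for Xdh, -0.01 to 0.10 for Pgr, -0.03 to 0.00 for Acaca and -0.01 to 0.01 for Ywhaz. Between the luminal classes, Itgb4 and Notch4 became 0.00 without TMM. Leaving out libraries gave -0.49 to 0.26 for Actg2 (above 0 without luminal replicate 2), -0.06 to 0.02 for Itgb4, -0.09 to 0.01 for Notch4, -0.00 to 0.04 for Tcf4, -0.00 to 0.05 for Slc2a1 and -0.15 to 0.00 for Mcam. Among lists far from the threshold, the Notch list turned direction with cells matching their sort (adjusted p = 0.93) and with gene bodies alone (0.98), and the endothelial list with gene bodies alone (0.94). Leaving out libraries gave adjusted p-values (camera) of 0.91 to 0.99 for Notch and 0.83 to 0.99 for endothelial markers between the sorts, and of 0.92 to 0.95 for pan-luminal and 0.83 to 0.95 for endothelial genes between the classes.

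Whether the replicate numbers pair the libraries cannot be told here. Deviations of same-numbered libraries had correlations of 0.03, -0.02 and -0.02, and not every library correlated best with its own number. Libraries of a sort differed on average by no more than sampling noise, so a shared origin could hardly show in these correlations. With the number as a replicate block 99018 peaks, 20144 genes and 8 lists passed, and without the block 15641 genes and 2 lists passed between the classes. The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. Only 1 of the 10, the real one, called as much: it called 100867 peaks and 20426 genes and the highest other split 0 of either (edgeR; 122 peaks and 25 genes at an unadjusted p under 0.05). For lists the real split called 8 and the highest other 7, and every other split still sets 2 basal against 2 luminal libraries. Between the classes, 4 exchanges are too few as well: 15702 genes were called against at most 0 (5 unadjusted), and 3 of the 4 exchanges called 2 lists. The other exchanges mix the classes in the same way. The minimum of 2000 counts removed no cell and tests nothing. Not run, for lack of a genome sequence and of transcription starts here, were motif sets in both comparisons, GC offsets alone or with the block, windows of 1 kb around transcription starts for genes and lists, and promoter, exon and intron classes. A second overlap rule for peaks was not needed with 1 shared peak list. Depth limits what luminal replicate 1 (19933799 counts) and the 35 basal-like cells in luminal libraries can show.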

Other observations

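Tests chosen after the result was seen were the one on basal cells among secretory-like cells and those on single sub-clusters of cluster 4. In each of the 3 epithelial classes, clustered separately, 1 sub-cluster had Il1rapl1 first and Cdk8 and Slc22a29 among its leading genes. Whether these 3 sub-clusters are 1 cell state was not tested. Among secretory-like cells of luminal libraries it held 297, with a median of 8198 counts, the lowest of the class (others 11366 to 15704). Among hormone responsive-like cells of luminal libraries it held 540, with a median of 9010.5 counts, again the lowest (others 10582 to 24231). Among basal-like cells of basal libraries it held 2665, with a median of 19178 counts (others 9681 to 23044.5). In secretory-like and hormone responsive-like cells Sgcd was among its leading genes too. Each of the 3 was found in every library of its sort, in this order at 3.83% to 5.04%, 7.09% to 7.96% and 18.2% to 20.2% of all cells. These genes define the sub-clusters and were chosen after their values were seen, so they are values and not a tested difference. Epithelial cells of the class that their sort should exclude were few, with 92 luminal-like cells in basal and 35 basal-like cells in luminal libraries. Of these, 0 and 1 shared a barcode with a library of the other sort, against 241 of 21133 other cells. Secretory-like cells of basal replicates 1 to 3 had median counts of 23547.5, 24905 and 19586, against 12731.5 to 15047 in luminal libraries. Hormone responsive-like cells had 13371, 17510 and 10273, against 12082 to 15175 in luminal libraries. Whether these cells of the basal libraries are doublets was not tested.

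Genes more open in basal libraries tended to be more open in secretory-like than in hormone responsive-like cells. Of 2484 genes over 2-fold higher in basal libraries, 2119 were compared between the classes. Among these, 913 were higher in secretory-like and 452 in hormone responsive-like cells (edgeR). Their median log2 difference (hormone responsive minus secretory) was -0.28, against 0.01 for all genes and -0.01 for genes over 2-fold higher in luminal libraries. Basal cells or their DNA among the secretory-like cells would have to bring 2.65% of the basal profile to take off 50% of this median, which is 29 CPM over the 12 named basal genes, and these had 104.8 CPM in secretory-like and 98.5 CPM in hormone responsive-like cells. That excess of 0.576% (bootstrap SE 1.27 over genes), like the 1.55% (SE 0.679) of the 100 more open genes lowest in both classes together, lay below the need but within 2 SE of it, so this explanation stays open, and removing the excess left the median at -0.25 and -0.20. Regions open in both basal and secretory cells may also underlie the pattern, a hypothesis found on these data that was not tested itself.

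Among hormone responsive-like cells of the luminal libraries, 310 cells formed a sub-cluster with 9 secretory markers raised, led by Rftn1 and Kit, at 3.27%, 4.86% and 3.88% of luminal replicates 1 to 3. Doublets of a secretory-like and a hormone responsive-like cell are a candidate explanation. Such cells should be open at no gene beyond both classes, and 0% of 24774 genes lay at least 1.5-fold outside both (edgeR glmTreat, adjusted p under 0.05; 12 genes at an unadjusted p under 0.05), while 857 and 1175 genes differed from the one and the other class. The median count, known before the test, was 2.31, 1.95 and 1.87 times the mean of both classes, and the doublet score was 0.9 to 0.933 against 0.233 to 0.333. A cell state between the classes would also lie between them and stays open, and the share is above the 0.402%, 1.42% and 0.804% that a nominal rate of 0.8% doublets per 1000 barcodes gives for such pairs.

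Cluster 4, most of whose cells were in basal libraries, divided into 4 sub-clusters over all libraries, and doublets of a basal cell with another cell were weighed by the median level of the 12 basal keratin and identity genes relative to basal-like cells. At least 0.35 was set as what doublets need and under 0.2 as what excludes them, jointly for sub-clusters 4.2 to 4.4 before their values were seen. Sub-cluster 4.2 missed that bound and left the joint test undecided, so the verdicts per sub-cluster were made afterwards. Sub-cluster 4.1 (204 cells, led by Krt14) had 0.569, with pericyte markers at 46.8 CPM (22.6 in basal-like cells), as doublets or basal cells of another state may give, and 4.2 (126 cells, 8 of 12 endothelial markers raised) had 0.231, which does not decide. Sub-clusters 4.3 (92 cells, 7 of 10 pericyte and 12 of 28 basal markers raised, led by Abcc8) and 4.4 (67 cells, 8 of 12 endothelial markers raised, led by Lalba) had 0.104 and 0.163, a median lower than set for doublets although single genes reached 1.42 and 1.74. Their leading genes also included the contractile gene Myocd in 4.3 and the endothelial markers Sox17 and Cldn5 in 4.4. What 4.3 and 4.4 are stays open, with pericyte markers at 52.7 CPM and contractile genes at 1.11 times the basal-like level in 4.3 and, despite the CD31 stain, endothelial markers at 62.7 CPM (15.1 in basal-like cells) in 4.4. The median doublet score was 0.433, 0.4, 0.233 and 0.3 in sub-clusters 4.1 to 4.4. Sub-clusters of basal-like cells had 0.233 to 0.533, so the score did not set cluster 4 apart.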
